A study of Cyprinus carpio with 18 samples.

How the data were processed

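The data are 18 small RNA libraries of carp embryos and larvae, 3 for each of 6 stages, grouped by the stage that the labels give. Per the labels' protocols, total RNA was extracted with TRIzol, RNA of each stage was pooled in equal amounts, adapters were ligated, and libraries were sequenced as 50 bp single-end reads on a HiSeq 2500. Because nothing in the labels says that the 3 libraries of a stage came from separate spawnings or batches of embryos, the p-values measure the spread between these libraries, which may be technical. Replicates of a stage differed by far more than sampling noise, with a chi-square per degree of freedom of at least 51.95 for any pair, so none was taken for a repeat deposit of another. Repeat libraries made from the same pool of RNA can also differ by more than sampling noise, so the value does not show that they are separate samples.

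The authors deposited raw counts per mature microRNA for each library, whole numbers with no normalization. Per the submitters' processing notes FastQC and edgeR were used by the authors. The aligner, the genome build and the program that predicted microRNAs are not given in the sources used here, nor is how reads shared by near-identical family members, such as those of let-7, miR-29 or miR-10, were assigned, so single members of such families are uncertain. In the values themselves, the named microRNAs are listed with their zeros (2 were 0 everywhere), while the 2742 predicted ones appear in a library only from 5 counts up and were taken as 0 otherwise. The authors also deposited TPM values for the series. In that table the TPM values of a library are proportional to its counts, with no length term, to within 0.0839%, and the library totals they imply exceed the listed counts by the shares given under the results for a closer look. The TPM values were used for these totals and not for tests.

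Depth per library ranged from 60779 to 8427601 counts, so that 1 TMM-scaled CPM stood for 0.0510 counts in the library with the lowest effective depth and 16.1 counts in the one with the highest. Counting intervals and floors (3 counts over the 3 libraries of a stage) cover counting error only, since reads without molecular identifiers are not independent molecules. Counting intervals are exact 95% intervals of a ratio of counts.

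Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Counts were scaled with TMM factors, filtered with filterByExpr by stage (count minimum 10), and fitted with 1 mean per stage over all 18 libraries with glmQLFit (robust) and glmQLFTest. There were 12 residual degrees of freedom and a common biological coefficient of variation of 0.855. P-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05, and all adjusted p-values of single microRNAs come from this test unless another tool is named. Standard errors were derived as the absolute log2 fold change over the square root of the quasi-likelihood F. TMM factors were 0.195 to 0.422 for blastocyst libraries, 0.281 to 0.711 for gastrulation, 0.884 to 2.24 for cleavage and 1.22 to 1.92 for the later stages. Shares, numbers detected (thinned to 60779 counts, mean of 20 draws) and the share of the top 10 were compared with permutation tests of the F ratio (100000 permutations). Their p is the share of permuted F ratios at least as large as the observed one. They were run in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

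Lists of microRNAs were fixed by family number: miR-430, let-7, miR-100 and miR-125, muscle, brain, sensory hair cell and retina, eye, epithelium, blood, liver, gut and kidney, pancreas and endocrine, cartilage and mesenchyme, endothelium, Hox cluster, miR-17-92 and paralogs, gonad, and stress and immune. The 14 lists with at least 2 tested members were tested with camera, with the correlation estimated per list and Benjamini-Hochberg adjustment over lists and comparisons, and the miR-430, eye and liver lists have 1 member each. Only named microRNAs are discussed by name, under this rule: (a) in each comparison the 5 largest rises and 5 largest falls among those past the threshold with a stage mean of at least 100 TMM-scaled CPM and no overlap between the libraries of the stages; (b) the 2 most abundant members of each list; (c) the 10 most abundant overall; (d) the 3 most abundant per stage. Exceptions are marked as chosen after their values were seen. Groups, tests, lists, the naming rule and the first set of alternatives were fixed before the data were examined.

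That first set held RLE size factors, TMM with singleton pairing, library totals, no filter, at least 10 CPM in 3 libraries, DESeq2 1.42.0, an added minimum log2 fold change of 1, each library left out with the filter redone (394 to 448 microRNAs tested), the replicate number as a block, the 2 stages alone, camera with a preset correlation of 0.01, fry, and other settings of the 3 measures per library. Added after seeing the data were named microRNAs only, unlisted predicted microRNAs counted as 4, the totals behind the TPM values, thinning to the smallest library, subtraction of the hatching and larva profile from earlier libraries, leaving out blastocyst 2, blastocyst 3 and gastrulation 2 with the filter redone (497 tested) and with the same 328 microRNAs, and each library left out with the same 328. The last 2 keep the effect of a library apart from that of the filter.

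The test was tried on simulated data of 328 microRNAs, in which 60 were changed, since 200 would have been most of them. The first-named stage was given the mean profile of the other stage, scaled to its own TMM-adjusted totals, with as many rises as falls. The simulated blastocyst therefore lacked the high miR-430 share of the real one. For blastocyst against cleavage it called 2 of 30 changed 4-fold and 9 of 30 changed 16-fold. For hatching against organ formation it called 2 of 30 and 16 of 30. It made 0 false calls in both, which does not cover errors from a scale set by miR-430. The permutation test was under 0.05 in 4 of 100 simulations with no difference and in 20 of 20 with steps between stages. The steps were large and equal from stage to stage, so the latter does not show its power at smaller differences.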

Results

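Small RNA was sequenced from whole embryos of the common carp (Cyprinus carpio) at 6 stages of development, with 3 libraries per stage and 18 in all. The fish were of the FFRC No.2 strain, a selected farmed strain, and spawned naturally. The stages were cleavage (2 h after fertilization), blastocyst (6 h), gastrulation (12 h), organ formation (20 h), hatching (64 h) and larva (1 day after hatching). MicroRNAs, the short RNAs that repress the messenger RNAs they pair with, were the molecules counted. The design follows their levels through development, so each stage was compared with the stage before it, and the larva was compared with cleavage. The counts covered 2888 microRNAs, 2742 of them predicted ones known only by sequence and the rest known by name in carp, given here without their species prefix ccr-. Of these, 127 named and 201 predicted microRNAs, 328 together, were abundant enough to test. No genome position is given for any of them in the sources used here.

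Sequencing depth differed widely between stages. Total counts were 94306 to 135739 per library at cleavage, 369985 to 438398 at blastocyst, 157111 to 250751 at gastrulation and 60779 to 141161 at organ formation. At hatching they were 4964459 to 6694561, and in the larva 5642188 to 8427601. All named microRNAs with any count were detected in each hatching and larva library, against 116 to 136 of them per library at the earlier stages.

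miR-430, which in fish is switched on with the embryo's own genome and clears maternal messenger RNA, made up 0.691% ± 0.750 (SD, n = 3) of the counts at cleavage and 75.1% ± 4.05 (SD, n = 3) at blastocyst. Its share was 51.95% ± 11.8 at gastrulation, 33.2% ± 4.44 at organ formation, 5.86% ± 0.857 at hatching and 1.45% ± 0.897 in the larva (SD, n = 3 each). The shares differed between stages in a permutation test of the F ratio (F = 96.05, p = 1e-05, the smallest that 100000 permutations can give). miR-738 was the most abundant microRNA at cleavage, at 53.6% ± 20.1 (SD, n = 3), with a lowest library of 37.3%. As a share of all counts, of which miR-430 took a varying part, it stood at 12.3% at blastocyst, 29.6% at gastrulation, 15.0% at organ formation, 0.270% at hatching and 0.175% in the larva. miR-26a and miR-143 followed it at cleavage, with 3.12% ± 1.44 and 2.89% ± 1.75 of the counts (SD, n = 3). miR-199-5p, a microRNA of mesenchyme and skeleton, and miR-10b, encoded inside a Hox gene cluster, led at hatching with 10.1% and 10.01%. In the larva miR-199-5p held 13.8%, miR-181a 6.45% and miR-10b 5.53%.

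**Figure D1:**
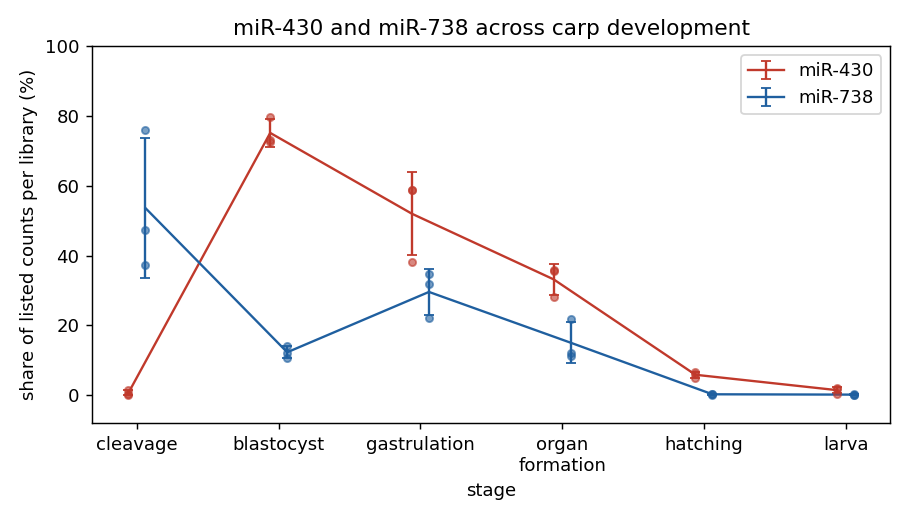
Share of listed counts (percent, y axis) taken by miR-430 and miR-738 at each stage (x axis), with points for the 3 libraries per stage, lines through the stage means and bars of 1 SD. miR-430 goes from 0.691% at cleavage to 75.1% at blastocyst and 1.45% in the larva, and miR-738 from 53.6% at cleavage to 0.175% in the larva.

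Few microRNAs dominated the early libraries. The 10 most abundant microRNAs of each library held 73.3% ± 11.1 of its counts at cleavage, 92.9% ± 3.51 at blastocyst and 89.9% ± 4.10 at gastrulation (SD, n = 3 each). Their share was 73.9% ± 5.46 at organ formation, 54.7% ± 1.83 at hatching and 50.96% ± 0.512 in the larva (F = 28.9, permutation p = 3e-05). With every library thinned to 60779 counts, 394 ± 102 microRNAs were detected at cleavage, 270 ± 32.1 at blastocyst, 215.6 ± 25.1 at gastrulation and 214.9 ± 26.0 at organ formation. The numbers were 370 ± 14.8 at hatching and 355 ± 2.00 in the larva (SD, n = 3 each; F = 8.98, permutation p = 0.00114). Predicted microRNAs under 5 counts are left out of each library's list, which lowers the number in shallow libraries even after thinning. With a minimum of 5 counts the order of stages differed, with 119 ± 26.5 microRNAs at blastocyst, 176 ± 6.04 at organ formation and 166 ± 1.81 at hatching (SD, n = 3 each).

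From cleavage to blastocyst, miR-430 rose by 9.42 on the log2 scale (SE 0.94, adjusted p = 2.455e-05, n = 3 libraries per stage). miR-17-3p, from the miR-17-92 cluster known for promoting cell proliferation, went from 2 counts to 51, a scaled ratio of 31.9 with a 95% counting interval of 8.38 to 270 (adjusted p = 0.00201). miR-9-5p and miR-9-3p, microRNAs of the developing brain, rose by 3.59 (SE 0.81) and 3.07 (SE 0.77). miR-206, a skeletal muscle microRNA, rose by 3.57 (SE 0.80), and miR-196b and miR-10d, both of Hox clusters, rose by 3.17 (SE 0.62) and 2.96 (SE 0.73). In blastocyst 1, 2 and 3 miR-206 had 27, 592 and 1203 counts, miR-9-3p 28, 323 and 1113, and miR-10d 18, 262 and 470. Scaled by TMM, blastocyst 1 lay within the range of the cleavage libraries for miR-206, miR-9-3p and miR-10d. They therefore did not meet part (a) of the naming rule at this step. miR-200a, a microRNA of epithelia, fell by 1.32 (SE 0.36).

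By group, 1 of 5 muscle microRNAs passed (4 adjusted over the list alone), 2 of 8 brain microRNAs (2 adjusted over the list alone) and 2 of 5 Hox cluster members (2). Of the miR-17-92 group 1 of 12 rose, and of the epithelial group 1 of 7 fell, with the same counts adjusted over the list alone. With library totals no muscle, brain or Hox cluster microRNA rose, the median of the brain list turned from 0.91 to −1.20 and that of the Hox list from 1.26 to −0.69, and 8 of the miR-17-92 group, all 7 epithelial, all 5 let-7 and all 4 stress microRNAs fell. With TMM no member passed in the let-7, miR-100 and miR-125, sensory, blood, gut, pancreas, cartilage, endothelium or stress lists. Beside the muscle and brain rises stands a measured feature of the libraries. The 15 muscle, brain, sensory and eye microRNAs had a median of 0.0439% and 0.0826% of their summed hatching and larva counts in blastocyst 2 and 3, against 0.00339% in blastocyst 1. In the cleavage libraries the median was 0.00826% to 0.0193%, in gastrulation 2 it was 0.0736%, and in gastrulation 1 it was 0.00877%. Blastocyst 2, blastocyst 3 and gastrulation 2 were left out in an alternative because these microRNAs were high in them, so it cannot test their rises. It leaves blastocyst 1 alone for its stage, taken to vary like the libraries of the other stages. Under that assumption, and with the same 328 microRNAs tested, 12 changed in place of 25, with miR-430 at 10.04 and miR-17-3p at 4.77 among them. With the filter redone on the 15 libraries, 497 were tested and 12 changed, again with miR-430 (10.16, adjusted p = 3.82e-05) and miR-17-3p (4.88, adjusted p = 0.0190). Over all alternatives the adjusted p of miR-430 lay between 1.60e-40 and 0.00905. That of miR-17-3p lay between 2.37e-05 and 0.0410 over the 51 alternatives that tested it, and its counts were too low for the filter in the fit of the 2 stages alone.

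edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 25 microRNAs, of which 20 rose (7 named) and 5 fell (2 named). The other named microRNA that fell was miR-34, named after its values were seen, with 21 counts at cleavage and 0 at blastocyst, at least 5.60-fold lower against a floor of 3 counts over the stage. miR-430 takes so much of the blastocyst libraries that the scale mattered. With library totals in place of TMM factors 110 microRNAs changed, 12 up and 98 down (12 and 90 with the totals behind the TPM values), and 4 of the 9 named calls were kept. Those lost were miR-206, at 1.57 (SE 0.91), miR-9-5p at 1.68, miR-9-3p at 1.02, and both Hox cluster microRNAs, miR-196b at 1.09 and miR-10d at 1.06. With the same 328 microRNAs tested, 10 changed without cleavage 1, 13 without blastocyst 3 and 37 without blastocyst 1, and without either of the first 2 libraries miR-206, miR-9-5p, miR-9-3p and miR-10d did not pass. These calls also ended without cleavage 2 for both miR-9 arms and miR-10d, and without cleavage 3 for miR-9-3p, at log2 fold changes over single omissions of 2.73 to 3.89 for miR-206 and 1.95 to 3.35 for miR-9-3p. The fall of miR-200a held in 21 of 52 alternatives, 12 of them among the 18 omissions of a library on the same microRNAs.

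From blastocyst to gastrulation, the named microRNAs that rose belonged to epidermis and to the miR-17-92 group. miR-203b-5p and miR-203b-3p, of a family that promotes differentiation of skin epithelium, rose by 3.73 (SE 0.79, adjusted p = 0.00925) and 1.83 (SE 0.51, adjusted p = 0.0464). miR-20a-3p and miR-17-3p rose by 2.93 (SE 0.82) and 2.41 (SE 0.66). miR-27c-3p fell by 1.90 (SE 0.38) and miR-22a fell by 1.63 (SE 0.31), while with library totals they had −1.19 (adjusted p = 0.156, over all alternatives 1.10e-06 to 0.646) and −0.98 (adjusted p = 0.156, over all alternatives 1.81e-07 to 0.238) and did not pass. miR-430 had a log2 fold change of −1.13 (SE 0.66, adjusted p = 0.355) and did not pass.

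These were 2 of 7 epithelial microRNAs (2 adjusted over the list alone) and 2 of 12 of the miR-17-92 group (3 adjusted over the list alone). In the stress list 1 of 4 fell adjusted over the list alone and 0 over all microRNAs, and no member of the other lists with at least 2 members passed either way. With RLE size factors 1 epithelial and 0 of the miR-17-92 microRNAs rose and 1 stress microRNA fell, and with library totals the fall in the stress list ended. Tested with edgeR's quasi-likelihood method, 23 microRNAs changed, 10 up (4 named) and 13 down (2 named). The split was 7 up and 15 down with RLE size factors, 13 up and 7 down with library totals, 8 up and 6 down with the totals behind the TPM values, and 17 up and 13 down with TMM paired over singletons. The rises of miR-203b-3p, miR-20a-3p and miR-17-3p held in 8, 10 and 14 of 52 alternatives. With the same 328 microRNAs tested, 14 to 22 changed with a blastocyst or gastrulation library left out, and the rise of miR-203b-5p passed in all 18 omissions, at 2.96 to 4.08. With at least 10 CPM as the filter, 460 were tested and the split was 5 up and 15 down. With the 3 libraries named above left out, and blastocyst 1 alone for its stage, 26 of the same 328 changed, of which 12 were among the 23.

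From gastrulation to organ formation, microRNAs of the Hox clusters rose. miR-196b rose by 3.26 (SE 0.55, adjusted p = 0.00218), miR-196a by 3.19 (SE 0.49, adjusted p = 0.00146) and miR-10c by 1.87 (SE 0.52, adjusted p = 0.0478), with n = 3 libraries per stage. miR-18c, of the miR-17-92 group, rose by 2.23 (SE 0.60). miR-122, the main microRNA of the liver, fell by 2.90 (SE 0.60), miR-738 fell by 2.88 (SE 0.80) and miR-430 fell by 2.56 (SE 0.69). The Hox cluster list as a whole took 1.07% ± 0.659 of the counts at gastrulation and 10.9% ± 5.19 at organ formation (SD, n = 3).

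Of the 5 Hox cluster members 3 rose (4 adjusted over the list alone), and of the 12 in the miR-17-92 group 1 rose (1 adjusted over the list alone). All 5 let-7 microRNAs, known as timers of late development, fell adjusted over the list alone, with a median log2 fold change of −1.73, but 0 passed over all microRNAs, and with library totals 0 passed over the list alone, at a median of −0.21 (0.03 with the totals behind the TPM values). As a share of the counts, let-7 stood at 0.617% ± 0.524 at gastrulation and 0.602% ± 0.455 at organ formation (SD, n = 3 each). Within these stages gastrulation 3 and organ formation 3 stood apart, with let-7a at 0.383% against 0.0816% and 0.161% in the other gastrulation libraries, and at 0.463% against 0.238% and 0.0658% in the other organ formation libraries. Adjusted over the list alone, 2 of 2 gut and kidney microRNAs and 1 of 2 blood microRNAs also fell, 1 of 7 epithelial microRNAs rose, and brain had 1 up and 1 down of 8. With library totals these gut, blood and brain falls ended over the list alone, and 4 epithelial and 7 miR-17-92 microRNAs rose over all microRNAs. The Hox list passed camera with a preset correlation of 0.01 (adjusted p = 9.385e-05) and fry (adjusted p = 0.00651). It did not pass camera, where adjusted p = 0.848 with an estimated correlation and the unadjusted p was 0.0189.

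Tested with edgeR's quasi-likelihood method, 20 microRNAs changed, 6 up (4 named) and 14 down (3 named). The split was 41 up and 6 down with library totals (50 and 6 with the totals behind the TPM values), where miR-430 had −0.65, miR-738 −0.98 and miR-122 −1.31 and none passed, and 13 up and 12 down with RLE size factors. The falls of miR-430 and miR-738 held in 13 and 15 of 52 alternatives, the rises of miR-196a and miR-196b in 50. With the same 328 microRNAs tested, 9 changed without organ formation 1, 10 without organ formation 2, 11 without gastrulation 1 and 34 without blastocyst 1, and 24 changed without blastocyst 2, blastocyst 3 and gastrulation 2. With the replicate number as a block 14 of the 20 calls remained, and those of miR-10c, miR-18c and miR-738 ended at 1.84, 2.21 and −2.82. In the 18 omissions on the same microRNAs miR-122 passed in all, at −3.41 to −2.49, miR-10c in 5, at 1.52 to 2.23, and miR-18c in 7, at 1.88 to 2.68.

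**Figure D2:**
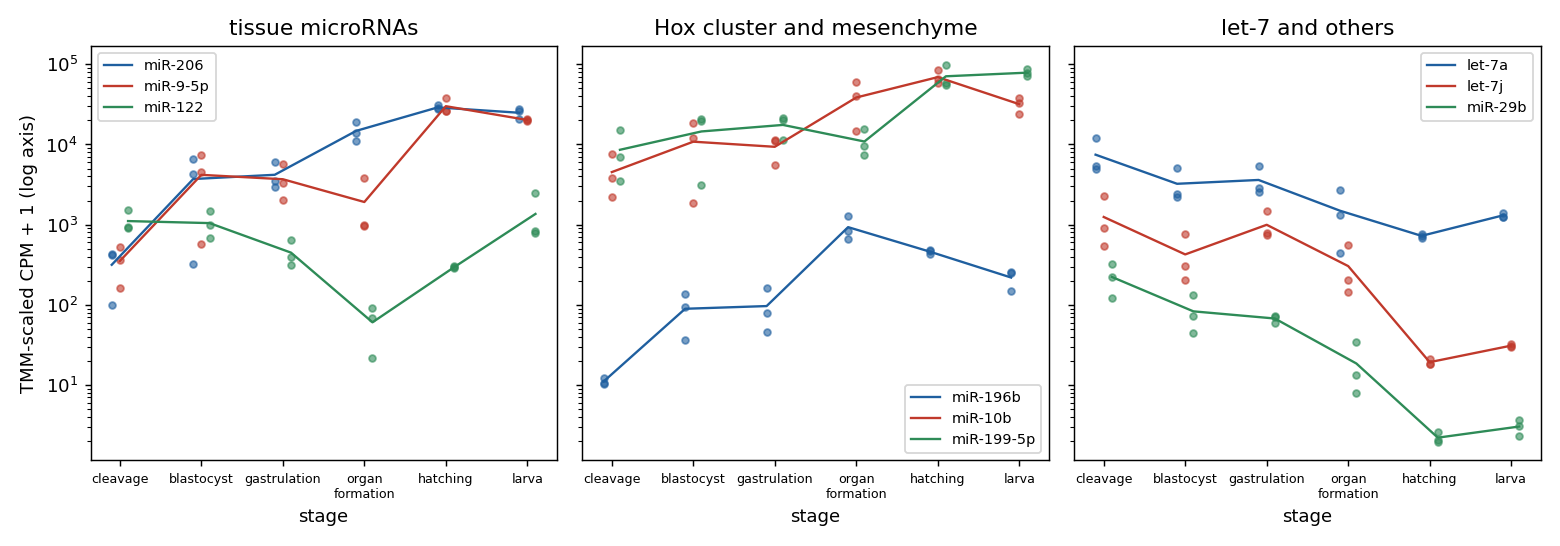
TMM-scaled CPM plus 1 (log y axis) of 9 named microRNAs at the 6 stages (x axis), with a point per library and lines through the means of the 3 libraries. miR-206, miR-9-5p, miR-196b, miR-10b and miR-199-5p end above their cleavage level, let-7a, let-7j and miR-29b end below it, and miR-122 is lowest at organ formation.

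From organ formation to hatching, 6 of 8 brain, 2 of 5 muscle, 2 of 4 sensory and 2 of 7 cartilage and mesenchyme microRNAs rose. miR-9-5p rose by 3.97 (SE 0.82, adjusted p = 0.00369) and miR-9-3p by 3.53 (SE 0.78, adjusted p = 0.00633), with n = 3 libraries per stage. miR-1, a microRNA of heart and skeletal muscle, rose by 3.07 (SE 0.62), and miR-133a-3p, also of muscle, by 2.50 (SE 0.76). miR-182-3p, of sensory hair cells and retina, rose by 3.05 (SE 0.82), miR-217, of the pancreas, by 2.85 (SE 0.58), and miR-199-5p by 2.70 (SE 0.65). miR-122 of the liver rose by 2.28 (SE 0.58).

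Falling at the same step, miR-738 fell by 5.51 (SE 0.90, adjusted p = 9.56e-04) and miR-430 fell by 2.34 (SE 0.69, adjusted p = 0.0213). miR-29a and miR-29b, which repress collagen messenger RNAs in vertebrates, fell by 4.19 (SE 0.96) and 3.75 (SE 0.76). let-7j fell by 4.06 (SE 0.70), miR-22b fell by 3.67 (SE 0.76) and let-7i fell by 2.58 (SE 0.69). All 7 turned to log2 fold changes above 0, from 0.02 for miR-738 to 3.41 for miR-430, when unlisted predicted microRNAs were counted as 4, which resets the scale of the shallow libraries. miR-29b had only 1, 3 and 3 counts in the organ formation libraries, against 11, 6 and 13 at hatching. Counts of miR-22b per library were 16 to 151 at organ formation and 187 to 242 at hatching. The hatching libraries were far deeper, so an effect of depth on the falls at this step cannot be told apart from one of stage.

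Of 8 brain microRNAs 6 rose, of 5 muscle microRNAs 2 rose, and of 4 in the miR-100 and miR-125 list 3 rose, each with the same count adjusted over the list alone. Of 4 sensory microRNAs 2 rose (4 adjusted over the list alone), of 2 endothelial ones 1 rose (2), and 2 of 4 pancreatic and 2 of 7 cartilage microRNAs rose (2 and 2). 1 member each rose in the Hox (1), miR-17-92 (0) and stress (1) lists, and 2 of 5 let-7 microRNAs fell (3). miR-184, of the lens and cornea and the single eye microRNA measured, rose by 1.24 (SE 0.36, adjusted p = 0.0213), with a log2 fold change of 0.48 under RLE size factors that did not pass. No epithelial, blood or gut microRNA passed. With RLE size factors 4 brain, 1 muscle, 1 sensory, 1 cartilage, 1 pancreatic and 0 endothelial microRNAs rose, the Hox and miR-17-92 lists turned to 2 and 3 falls with no rise, 1 blood microRNA and 4 let-7 microRNAs fell, and the rises of miR-122 (1.58) and miR-133a-3p (1.71) ended. With library totals 3 brain, 1 muscle, 1 sensory, 1 cartilage, 1 pancreatic, 1 of the miR-100 and miR-125 list and 0 Hox, miR-17-92 or endothelial microRNAs rose, and the rises of miR-133a-3p (2.28) and miR-184 (1.11) ended. The brain list passed camera with the preset correlation (adjusted p = 0.0109), while adjusted p = 0.848 with an estimated correlation and the unadjusted p was 0.0385. fry, which asks whether the members of a list move one way, passed for brain (adjusted p = 1.996e-04), pancreas, miR-100 and miR-125, sensory and muscle, and not for cartilage (adjusted p = 0.0569). With camera, adjusted p = 0.848 with an estimated correlation for each of these 5 lists, and adjusted p = 0.930 for cartilage. The 15 muscle, brain, sensory and eye microRNAs had a median of 0.0274% to 0.0909% of their summed hatching and larva counts in the organ formation libraries.

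edgeR's quasi-likelihood test called 89 microRNAs, 60 up (31 named) and 29 down (8 named). The split was 36 up and 43 down with RLE size factors, and 38 up and 30 down with library totals. The filter, which also resets the TMM scale, mattered for the count and the balance, with 48 up and 32 down at a minimum of 10 CPM (460 tested) and 5 up and 19 down with no filter (2886 tested). With the same 328 microRNAs tested, leaving out 1 library gave 63 to 94, lowest without organ formation 1, hatching 1 or hatching 2, and falls outnumbered rises only without cleavage 1, with 40 up and 41 down. Without blastocyst 2, blastocyst 3 and gastrulation 2 the split was 48 up and 35 down. Rises of miR-133a-3p, miR-182-5p, miR-184 and miR-126-3p held in 26, 18, 20 and 9 of 52 alternatives, against 51 for the rise of miR-9-5p and the falls of miR-738, miR-29a, let-7j and miR-22b. In the 18 omissions on the same microRNAs the rises of miR-9-5p, miR-9-3p (2.88 to 3.94) and miR-1 (2.41 to 3.51) passed in all, while the fall of miR-430 ended without organ formation 2 or any of the 3 hatching libraries, at −3.01 to −2.18.

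From hatching to larva no named microRNA passed edgeR's quasi-likelihood test. miR-122 of the liver had a log2 fold change of 2.21 (SE 0.56, adjusted p = 0.145, n = 3 libraries per stage), and miR-192 and miR-194, of gut, liver and kidney, had 2.41 (SE 0.92, adjusted p = 0.263) and 2.36 (SE 0.95, adjusted p = 0.272). miR-430 had −2.22 (SE 0.68, adjusted p = 0.171). The share of miR-192 was 2.29% ± 2.17 in the larva and 0.343% ± 0.0243 at hatching (SD, n = 3), so the spread between larva libraries was close to their mean. Larva 3 stood apart. In larva 1, 2 and 3 miR-192 had 60647, 62614 and 404205 counts, miR-194 6128, 6823 and 46755, and miR-122 7796, 8344 and 39634. The totals of these libraries were 5642188, 6252718 and 8427601.

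The 2 gut and kidney microRNAs passed adjusted over the list alone, and no member of the other lists did. Over all microRNAs 1 changed, a predicted one of sequence GTGTGGAGAGCCGTTTGTTAC, singled out after its values were seen (adjusted p = 2.122e-06). It had 1676 to 5108 counts in each library up to organ formation, where it held 4.41% ± 1.06 of the counts (SD, n = 3), and 395 to 775 counts at hatching. It was unlisted, and so had at most 4 counts, in all 3 larva libraries, at least 225-fold lower than at hatching. With the same 328 microRNAs tested, 1 to 5 changed with 1 library left out, the most without blastocyst 1. At an unadjusted p under 0.05 there were 46 microRNAs, 14 of them named. DESeq2 called 29 microRNAs, 16 of them named. A fit of these 2 stages alone, which takes the spread from 6 libraries that are all deep and tests 612 microRNAs, called 49 of them, 32 up and 17 down, with 25 named. In that fit, listed here after their values were seen, let-7a and let-7g rose by 1.15 (SE 0.17) and 1.45 (SE 0.24), and miR-10b and miR-10c of the Hox clusters fell by 0.81 (SE 0.13) and fell by 0.70 (SE 0.11). miR-122 had 2.59 (SE 0.60) there and did not pass.

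Between cleavage and larva, muscle, brain and Hox cluster microRNAs rose and let-7, miR-29 and miR-738 fell. miR-206 rose by 6.31 (SE 0.91, adjusted p = 1.21e-04), miR-133a-3p by 5.67 (SE 0.89) and miR-1 by 4.65 (SE 0.66), with n = 3 libraries per stage. miR-9-5p rose by 5.86 (SE 0.90, adjusted p = 1.79e-04), miR-10d by 5.82 (SE 0.82) and miR-196b by 4.45 (SE 0.62). miR-129 had 2 counts at cleavage and 6524 in the larva, a scaled ratio of 46.03 with a 95% counting interval of 12.7 to 380 (adjusted p = 0.00110). miR-738 fell by 8.74 (SE 1.04, adjusted p = 4.62e-05), miR-29b fell by 6.73 (SE 0.82), miR-22b fell by 5.58 (SE 0.82) and let-7j fell by 5.38 (SE 0.74). miR-142-5p, a microRNA of blood cells, fell by 5.14 (SE 0.85). Counts per library at cleavage and larva were 80 to 493 and 270 to 503 for let-7j, and 68 to 560 and 266 to 423 for miR-22b. The larva libraries were far deeper, so an effect of depth on these falls cannot be told apart from one of stage.

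All 5 muscle microRNAs rose (5 adjusted over the list alone), and 7 of 8 brain microRNAs rose (7). Of 4 sensory microRNAs 3 rose (4), of 5 Hox cluster members 4 (5), of 7 cartilage and mesenchyme microRNAs 4 (4), of the miR-100 and miR-125 list 3 of 4 (3) and of the endothelial list 2 of 2 (2). All 5 let-7 microRNAs fell (5), with a median of −2.87, as did 1 of 2 blood (1) and 2 of 4 stress microRNAs (2). With unlisted predicted microRNAs counted as 4 the direction turned for let-7a (3.49), let-7g (3.23), let-7i (1.85), let-7j (0.65), miR-142-5p (1.01), miR-21 (4.29), miR-22b (0.37) and miR-29a (1.18). The miR-17-92 group had 4 up and 2 down of 12 (4 and 2), the pancreatic list 1 up and 1 down of 4 (1 and 1), the epithelial list 1 up of 7 (1) and the gut list 0 (0). With library totals 4 let-7 microRNAs fell, 1 endothelial and 0 pancreatic microRNAs rose, and with RLE size factors the epithelial list had 1 up and 1 down and a median of −0.21 in place of 0.12. miR-184 of the eye rose by 1.87 (SE 0.37), while miR-122 of the liver had 0.30 (SE 0.54, adjusted p = 0.666) and miR-430 had 1.18 (SE 0.66, adjusted p = 0.138). The gonad list, which is the miR-202 family, had 0 measured members. Brain passed camera with the preset correlation (adjusted p = 0.0117), while adjusted p = 0.848 with an estimated correlation. fry passed for 10 lists, namely let-7, miR-100 and miR-125, muscle, brain, sensory, blood, cartilage, endothelium, Hox cluster and stress. With camera these 10 lists had adjusted p = 0.848 to 0.930 with an estimated correlation, so none passed there.

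In this comparison 200 microRNAs changed in edgeR's quasi-likelihood test, 102 up (51 named) and 98 down (27 named). miR-489 and miR-730, named after their values were seen, had 0 counts at cleavage and were at least 9.73-fold and at least 3.50-fold higher in the larva. With the same 328 microRNAs tested, leaving out 1 library gave at least 187, from 104 up and 83 down without larva 3 to 93 up and 111 down without blastocyst 1. The balance of rises and falls moved with the filter, which also resets the TMM scale. It was 121 up and 154 down at a minimum of 10 CPM (460 tested) and 52 and 78 with no filter (2886 tested). It was 159 and 70 in the 2 stages alone (380 tested), a fit that also takes its scale and spread from those stages only. The calls of miR-206, miR-9-5p, miR-133a-3p, miR-10d and miR-738 held in all 52 alternatives. Over all 6 stages 247 microRNAs changed, 93 named and 154 predicted, and leaving out 1 library with the same 328 tested gave 233 to 251.

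**Figure D3:**
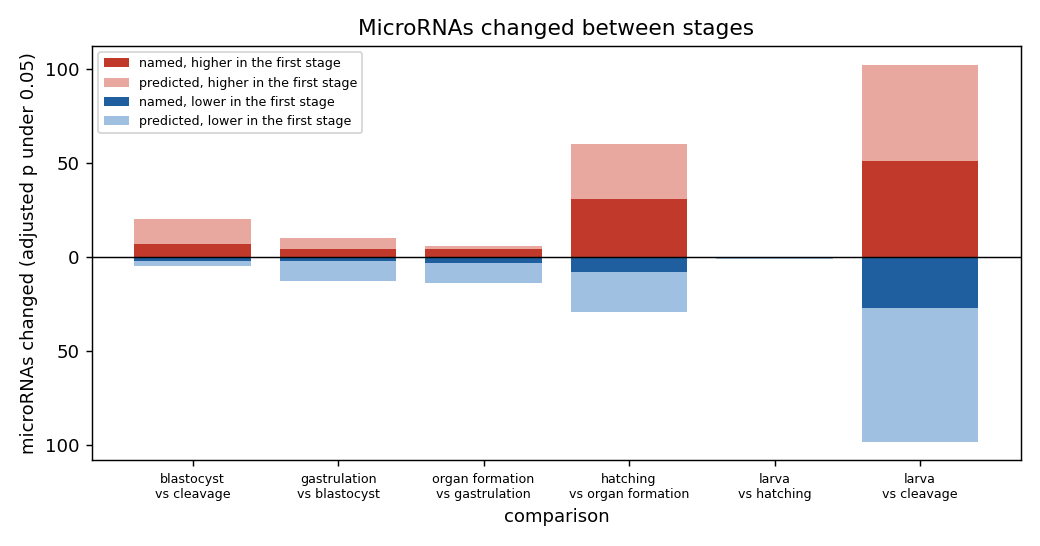
Number of microRNAs changed at an adjusted p under 0.05 in each comparison (y axis), bars up for those higher in the first-named stage and bars down for those lower, in dark colour for named and light for predicted microRNAs. Hatching against organ formation has 60 up and 29 down, larva against hatching 0 up and 1 down, and larva against cleavage 102 up and 98 down.

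Across the 6 comparisons, camera with an estimated correlation moved 0 of 14 lists in each. At an unadjusted p under 0.05 it had 1 list from gastrulation to organ formation, 1 from organ formation to hatching, and 0 elsewhere. Camera with the preset correlation moved 1 list in each of these 2 comparisons and 1 from cleavage to larva. fry moved 2, 5 and 10 lists in the same order, and both moved 0 in the remaining comparisons. From gastrulation to organ formation the 2 lists of fry were Hox cluster and blood (adjusted p = 0.0163). The direction of camera, which compares a list with the other microRNAs, and the sign of the median differed there for the brain, sensory, epithelial and endothelial lists. They differed from organ formation to hatching for the epithelial and Hox cluster lists, and from hatching to larva for muscle, brain and pancreas. The mean and the median differed in sign for the miR-17-92 and stress lists from organ formation to hatching, and for muscle and brain from hatching to larva. Relative to TMM, scaling by library totals shifted the median log2 fold change of all tested microRNAs by −1.99 from cleavage to blastocyst, 0.52 to gastrulation, 0.73 to organ formation, −0.16 to hatching and 0.16 to larva, and by 0.12 from cleavage to larva.

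**Figure D4:**
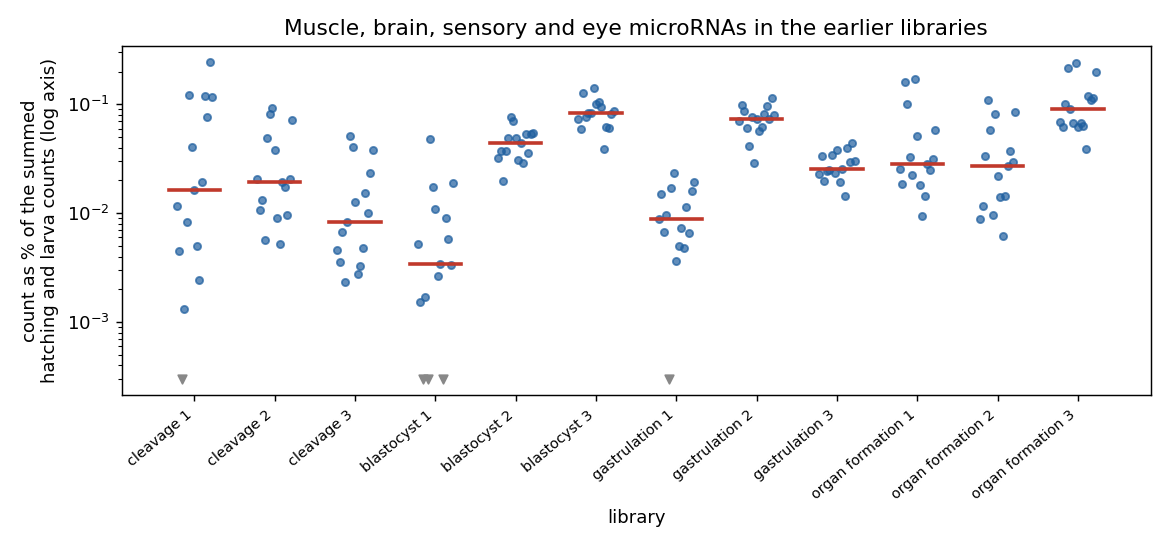
Counts of the 15 muscle, brain, sensory and eye microRNAs in each of the 12 earlier libraries (x axis), as percent of their summed counts at hatching and larva (log y axis). Points are microRNAs, triangles at the bottom mark counts of 0 and bars are medians, which lie at 0.0439% in blastocyst 2, 0.0826% in blastocyst 3 and 0.0736% in gastrulation 2.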

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

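Of the tests in this part, the one on the scale set by miR-430, both on miR-738 and the carry-over test on gastrulation 3 and organ formation 3 were chosen after the result was seen, as was the subtraction. Reads behind the TPM values but outside the listed counts drew attention, as a signal in data that no comparison used. They made up 25.6% ± 7.43 of the reads at cleavage, 18.6% ± 1.36 at blastocyst, 24.3% ± 4.13 at gastrulation, 12.3% ± 3.71 at organ formation, 2.55% ± 0.0642 at hatching and 2.36% ± 0.2505 in the larva (SD, n = 3 each).

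Muscle, brain, sensory and eye microRNAs were present in blastocyst 2 and 3 and gastrulation 2 and 3 at a median per library of 0.0255% to 0.0826% of their later counts, against 0.00339% in blastocyst 1 and 0.00877% in gastrulation 1, and 3 of them rose from cleavage to blastocyst. A candidate explanation is reads or RNA carried over from the hatching and larva libraries, which would bring predicted microRNAs of those stages too. At 10 or more counts, 22, 32, 27 and 17 predicted microRNAs were expected in blastocyst 2 and 3 and gastrulation 2 and 3. These 98 are counted per library and repeat the same sequences, so at most 32 are distinct. Of the 98, 87.8% were listed. But 63.6% to 100% were listed in the other 8 early libraries as well, so the test is not specific to the 4. Subtracting the late profile decides nothing: it left 0 counts of the 3 at cleavage and, in blastocyst 1, 2 and 3, 0, 1 and 159 of miR-206, 0, 0 and 420 of miR-9-3p and 9, 95 and 408 of miR-9-5p. The 0 counts come from the subtraction and give no bound, what is left of miR-206 and miR-9-3p lies almost wholly in blastocyst 3, and the fitted log2 fold changes went from 3.57 (SE 0.80) to 13.9 (SE 4.34) for miR-206 and from 3.07 (SE 0.77) to 15.3 (SE 4.64) for miR-9-3p, whose calls ended as the SE grew more than the fold (adjusted p = 0.0845 and 0.102, over all alternatives 4.65e-06 to 1 and 2.73e-05 to 1), while miR-9-5p passed (adjusted p = 0.00684, over all alternatives 6.88e-07 to 0.803). With library totals 0 of the 3 passed, at 1.57 (SE 0.91), 1.02 (SE 0.92) and 1.68 (SE 0.91). But those totals shift the median of all tested microRNAs by −1.99 and leave the 3 above it by 3.01 to 3.67. The gap between libraries of a stage lies in the raw counts. Yet miR-430 held 79.8%, 72.6% and 73.0% of blastocyst 1, 2 and 3, at totals of 432581, 369985 and 438398. It held 58.7% and 58.9% of gastrulation 1 and 2. These values argue against the scale set by miR-430 as the source of that gap. For the rise from cleavage to blastocyst, that scale, carry-over and early transcription in the embryo all stay open.

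As a share of all counts, miR-738 was highest at cleavage. Of these counts miR-430 took 0.691% at cleavage, 75.1% at blastocyst and 51.95% at gastrulation. The counts of miR-738 per library were 44619 to 77411 at cleavage, 39592 to 61008 at blastocyst and 54467 to 57691 at gastrulation. In cleavage 1, 2 and 3 miR-430 took 473, 1463 and 177 of 135739, 94306 and 101777 counts. In gastrulation 1, 2 and 3 it took 106433, 147632 and 60143 of 181323, 250751 and 157111. For counts outside miR-430 the ranking therefore did not hold. There the mean share of miR-738 was higher at gastrulation than at cleavage, with libraries that overlapped. For the share of all counts, low depth stays open. Organ formation libraries reach lower totals, and their highest share of all counts was 21.8%. That is below the lowest cleavage share of 37.3% by more than the SD of 5.91. A stricter bound that was set before this one, a mean below that lowest share divided by 3, was not met by the mean of 15.0%. Neither bound can decide, since miR-430 held 28.0% to 35.9% of the organ formation libraries and 0.174% to 1.55% of the cleavage ones. This lowers the share left for miR-738 at organ formation, and the stages differ in more than depth. Fragments of other RNA read as miR-738 may contribute. Over the 12 earlier libraries, centred by stage, its share of counts outside miR-430 followed the share of unlisted reads (r = 0.779, permutation p = 0.0146, adjusted 0.0292 over 2 relations; rho = 0.664, permutation p = 0.0390; r = 0.577 without the 2 libraries farthest out). A maternal supply of miR-738 also stays open and was not tested.

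In gastrulation 3 and organ formation 3, let-7, miR-192, miR-194, miR-143 and miR-99 stood above the other libraries of the stage, with a median excess of 1.58 and 1.82 on the log2 scale over 9 members. Carry-over from the late libraries is argued against as the whole source of this excess, since the excess alone, as a fraction of the late counts, was 22.1 and 6.61 times the whole fraction of muscle and brain microRNAs, at 11.6 or more and 2.56 or more in each member, while the ratio of the full levels is no test, as it passed the bound of 4 in 5 of the 6 libraries of these stages. RNA shared with the cleavage libraries may be involved or not: across the 127 named microRNAs, which are not independent, the excess correlated with the profile of cleavage at r = 0.114 and 0.159, too weak to decide. No biological explanation was tested.

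Regrouping the 6 libraries of each comparison gives 10 splits, too few for a share under 0.05. The real split was the 1 with the most calls in each, and the highest other count was 6 against 25 for blastocyst and cleavage, 3 against 23 for gastrulation and blastocyst and 2 against 20 for organ formation and gastrulation. It was 0 against 89 for hatching and organ formation, 0 against 1 for larva and hatching and 0 against 200 for larva and cleavage. Over all stages 1 of 100 regroupings, the real one, gave 247, and the highest other gave 13. Mixed groups carry the differences between stages in their spread, which lowers their counts. The 3 libraries of a stage may also be repeats from the same pool of RNA. Shuffling libraries therefore cannot exclude chance differences between pools as a source of that count.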

How the results depend on the processing

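The named-only, counted-as-4, TPM-total, thinned, subtracted and 3-library settings and the omissions on the same 328 microRNAs were chosen after seeing the data. The cause of a shift was not tested except where a setting changes what is tested. The F tests of the 3 measures per library passed in every alternative. With 1 library left out F was 7.35 to 35.4 for detection (the highest without cleavage 3), 23.5 to 77.2 for the top 10 (the highest without cleavage 3) and 76.4 to 416 for miR-430 (the highest without gastrulation 3).

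With 1 library left out and the filter redone, which raised the number tested from 328 to between 394 and 448, counts ranged over 9 to 31 for blastocyst against cleavage, 9 to 22 for gastrulation against blastocyst, 8 to 25 for organ formation against gastrulation, 24 to 102 for hatching against organ formation, 1 to 3 for larva against hatching (3 without larva 1), up to 278 for larva against cleavage and 254 to 309 for any stage, and camera moved 0 lists each time. With 1 library left out and the same 328 tested they were 10 to 37, 14 to 24, 9 to 34, 63 to 94, 1 to 5, at least 187 and 233 to 251 in that order, so part of the first ranges comes from the filter. In the same order of comparisons, library totals gave 110 for blastocyst against cleavage and 47 for the third. No filter, with 2886 microRNAs tested, gave 6, 4, 24 and 130 for the second, the third, the fourth and the sixth, and 1 list for the third. At least 10 CPM gave 2 for larva against hatching. DESeq2 gave 49, 43 and 61 for the first 3 and 29 for larva against hatching. The 2 stages alone gave 10, 11 and 32 for the first 3, 1.6e+02 (99 up and 56 down) for the fourth and 49 for larva against hatching.

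The replicate number as a block gave 13 for gastrulation against blastocyst and 2 for larva against hatching, and F tests permuted within numbers gave permutation p = 0.00372, 4.1e-04 and 1e-05, the last the smallest they can give. Over all tested microRNAs no same-numbered pair of libraries correlated above 0.1 (highest 0.0960), but over 86 abundant named ones the pairs of organ formation and gastrulation had 0.247, 0.357 and 0.697, so whether the numbers pair those libraries is open. The block there kept 14 of 20 calls, 4 of 7 among the named.

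Named microRNAs only, which also resets the TMM scale, gave 16, 7, 38, 22 and 85 for the first, the second, the fourth, the fifth and the sixth comparison and 109 for any stage. The fourth had 16 up and 22 down, against 31 and 8 among the named ones in the main test, and shared 23 calls with those 39. The larger totals behind the TPM values gave 102, 14 and 56 for the first 3. Thinning gave 42, 14, 47 and 127 for the first, the second, the fourth and the sixth, and 160 for any stage. Subtracting the late profile gave 36 and 42 for the second and the third, and leaving out blastocyst 2, blastocyst 3 and gastrulation 2, with blastocyst 1 alone taken to vary like other stages, gave 12 and 53 for the first and the fourth with 497 tested, and 12 and 83 with the same 328. Among lists, the preset correlation gave 1, 1 and 1 and fry 2, 5 and 10 for the third, the fourth and the sixth comparison.

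Counting unlisted predicted microRNAs as 4 gave 2, 613, 136 and 668 for the third to sixth comparison and 798 for any stage. By construction it gives shallow libraries many equal values, which resets their TMM factors, and directions reversed. Hatching against organ formation then had 2.78 for let-7i, 1.32 for let-7j, 1.65 for miR-22b, 1.16 for miR-29a, 2.00 for miR-29b, 3.41 for miR-430 and 0.0222 for miR-738. Larva against cleavage had 3.49 for let-7a, 3.23 for let-7g, 1.85 for let-7i, 0.65 for let-7j, 1.01 for miR-142-5p, 4.29 for miR-21, 4.93 for miR-22a, 0.37 for miR-22b and 1.18 for miR-29a. Without blastocyst 2, blastocyst 3 and gastrulation 2 miR-9-3p had −0.0140 at blastocyst against cleavage (−0.0665 with the same 328 tested), a loss fixed by the choice of libraries. No other call of a microRNA named by the rule changed sign. Such calls held in 325 of 414, 166 of 311 and 918 of 1248 alternative values for the first, the second and the fourth comparison, ended in 139 of 364 for the third, and held in 1728 of 1871 for larva against cleavage. How far depth, apart from the spread between libraries, limits calls was not tested.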

Other observations

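Of the values in this part, all were chosen after seeing the data. Among the predicted microRNAs, 27 share the bases AAGTGC of miR-430 at positions 2 to 7, the seed that pairs with target messenger RNAs. Together they held 0.00566% ± 0.00980 of the counts at cleavage, 1.46% ± 1.14 at blastocyst, 0.236% ± 0.0784 at gastrulation, 1.65% ± 0.562 at organ formation, 0.262% ± 0.0718 at hatching and 0.0375% ± 0.0237 in the larva (SD, n = 3 each; F = 6.10, permutation p = 0.0171). Of 12 that were tested, 2 rose from cleavage to blastocyst, 1 rose from blastocyst to gastrulation, 1 fell from organ formation to hatching and 2 fell from cleavage to larva in edgeR's quasi-likelihood test. The organ formation share is not below the blastocyst share, while that of miR-430 itself goes from 75.1% to 33.2%, a difference in course that was not tested.

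The predicted sequences listed per library had a median length of 22 bases in each of the 18 libraries, and the share that begins with T (uracil in the RNA), the base common at the start of microRNAs, differed by stage. It was 59.2% to 65.4% of the sequences at cleavage, 50.7% to 53.1% at blastocyst, 38.9% to 44.2% at gastrulation, 39.4% to 44.05% at organ formation, 50.6% to 51.1% at hatching and 45.7% to 47.8% in the larva. Cleavage also had 276 ± 94.7 predicted sequences per library against 92 ± 25.9 at organ formation (SD, n = 3), at totals of similar size.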
